A study of Drosophila melanogaster with 6 samples.

How the data were processed

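Chromatin immunoprecipitation sequencing (ChIP-seq) libraries were made from ovaries of virgin Drosophila melanogaster females less than 6 h old, of wild-type flies (Canton S) and of the su(Hw)f mutant. The sample titles name the mutant f, and its strain label reads su(Hw)fv. su(Hw) encodes a zinc finger DNA-binding protein known for its part in the gypsy insulator. Per the labels, each genotype had an immunoprecipitation with guinea pig antibody against Su(Hw), a preimmune serum control and an input, with 1 sample in each group. Chromatin was fixed in 1.8% formaldehyde, libraries were amplified for 15 PCR cycles, and library fragments measured about 250 bp. The 2 immunoprecipitation libraries are not analysed here, so no binding of Su(Hw) was measured and the comparisons concern preimmune and input.

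The deposited values used are read counts per 100 bp window along the dm3 genome, one file per library, in wiggle format per the file headers. The values are whole numbers and were not scaled, so library totals differ. Genome build dm3 and Partek 6.5 come from the submitters' processing notes. The aligner, the treatment of duplicate reads and the treatment of reads with several matches are not given in the sources used here. Reads dropped because they matched several places leave repeated DNA at or near 0, and duplicates kept after PCR widen the scatter of counts beyond counting error.

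Windows were summed to 1 kb and 10 kb on the 6 major arms X, 2L, 2R, 3L, 3R and 4. Libraries were scaled to their reads on these arms. Levels given as multiples of a library median use its median 100 bp window instead, so comparing such multiples between libraries does not give the scaled ratio. A 10 kb window was called in the comparison of inputs when the genotypes differed at least 1.5-fold and the libraries held at least 50 counts together. A 1 kb window was called in the comparisons that involve preimmune at 2-fold and 20 counts. Adjacent 10 kb windows called the same way were merged into regions. With 1 library per group no test was run and no p-value is given. Ratios carry a 95% exact conditional interval (Clopper-Pearson), shares a 95% Clopper-Pearson interval, and a library with 0 reads a limit of 3 counts. These cover counting error only, and no difference between groups has a replicate check. The number of calls that counting error alone gives was taken from 20 binomial draws at the pooled rate.

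The scatter between neighbouring 100 bp windows on 3R was 3.68 times the Poisson value in wild-type preimmune, 1.72 times in wild-type input, 4.07 times in su(Hw)f preimmune and 2.69 times in su(Hw)f input. Structure along the arm and technical scatter were not separated, so the error of a single window may be wider than its interval.

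Calling was tested on simulated counts with known changes and Poisson scatter only. Among 120378 simulated 1 kb windows for wild-type preimmune over input, all 50 windows changed 3-fold were recovered, and 29 of 50 changed 2-fold, the threshold itself, while 68 unchanged windows were called. At 2-fold, 24 of 50 were recovered for su(Hw)f preimmune over input, with 65 unchanged windows called, and 28 of 50 for preimmune between genotypes, with 63. Among 12036 simulated 10 kb windows for input, all 50 changed 2-fold were recovered and 7 unchanged windows were called.

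Named regions followed rules fixed before the data were examined, apart from the choices stated here. For input these were the 10 longest merged regions, and ties in length, which the rule did not cover, were broken by the size of the ratio. For preimmune over input they were the 10 windows with the highest and the 5 with the lowest mean log2 ratio, among those changed at least 1.5-fold the same way in both genotypes. The rule had been written for gene promoters and was applied to 1 kb windows, since no dm3 annotation was used here. It ranked by the ratio of each comparison, and ranking by the mean over the genotypes was not part of it. For the same reason no gene names, gene lists, annotation classes, Su(Hw) motif sites, GC content or values at the su(Hw) locus are reported.

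Absent stretches and focal windows were defined by rules chosen after seeing the data. A 1 kb window was taken as absent in a genotype when its preimmune and input reads together came to under 5% of the scaled reads of the other genotype, which held at least 40. Absent windows were joined across up to 10 kb without a window at 25% or more. A focal window was a 500 bp window at 6 times the median of its library or higher, and those within 2 kb of each other were merged. In simulated counts for 120378 windows, the absence rule recovered 200 of 200 emptied windows and called 0 others. Recovery was assured, because those windows were emptied fully. The others had Poisson scatter only, so partial loss and false calls at the scatter of these libraries were not tested.

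Alternatives covered other scalings, count minimums and window sizes, and removal of windows with extreme counts. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.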

Results

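The data were read counts along the dm3 genome from ovaries of newly eclosed wild-type and su(Hw)f females, with 1 preimmune and 1 input library per genotype. Input is sheared chromatin before precipitation and reports DNA copy number and recovery, and preimmune is the chromatin that serum without the antibody brings down. The libraries held 12173312 reads (wild-type preimmune), 13993582 (wild-type input), 20130453 (su(Hw)f preimmune) and 20596448 (su(Hw)f input). Between 97.4% and 98.5% of reads lay on the major arms. The median 1 kb window held 97, 113, 170 and 155 reads in the same order, and the median 10 kb window held 1015, 1147, 1708 and 1638.

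Chromosome 4, a small and largely heterochromatic chromosome, stood apart from the large arms. Relative to input, preimmune held 1.62 times as many reads on chromosome 4 in wild type (95% interval 1.61 to 1.63) and 1.58 times in su(Hw)f (1.56 to 1.59). The heterochromatic scaffolds were higher in preimmune too, from 1.17-fold on XHet to 1.33-fold on 3LHet in wild type, and from 1.21-fold on XHet to 1.33-fold on 2RHet in su(Hw)f. The 5 large arms lay between 0.930 and 1.059 in wild type and between 0.941 and 1.048 in su(Hw)f.

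Between genotypes, chromosome 4 and heterochromatin were lower in su(Hw)f. The su(Hw)f to wild-type ratio on chromosome 4 was 0.752 in input (0.746 to 0.759) and 0.732 in preimmune (0.726 to 0.737). It was 0.662 and 0.684 on 2RHet, 0.820 and 0.817 on 3LHet, and 0.638 and 0.649 on the unplaced scaffold U. The 5 large arms stayed between 0.964 and 1.059 in either kind of library.

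**Figure D1:**
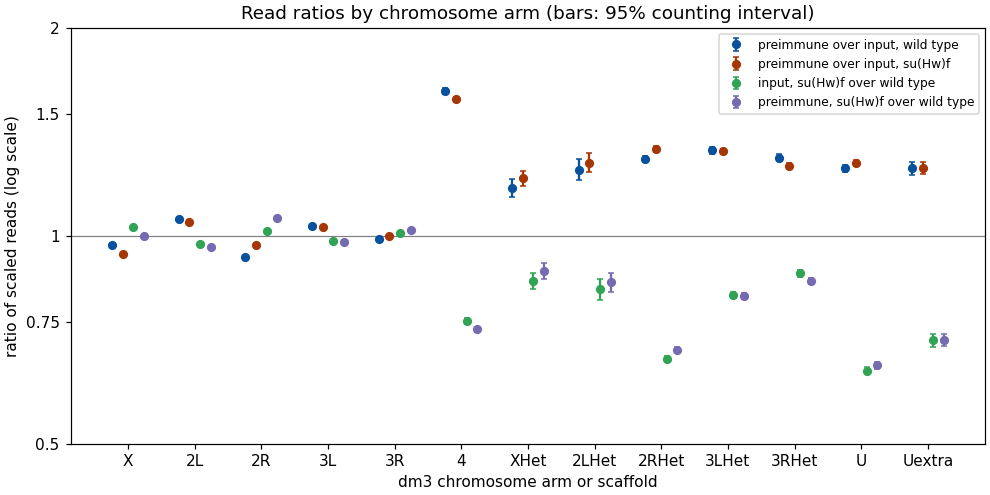
Ratio of scaled reads on each dm3 arm or scaffold (log axis) for preimmune over input in each genotype and for su(Hw)f over wild type in each kind of library, with 1 library per group; bars are 95% counting intervals. Chromosome 4 lies at 1.62 and 1.58 for preimmune over input, and at 0.752 and 0.732 for su(Hw)f over wild type.

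The comparison of inputs asked where the genotypes differ in DNA content. Wild type and mutant are different strains, so strain background and the su(Hw) mutation cannot be told apart in any comparison between them. Of 11901 windows of 10 kb, 35 were higher in su(Hw)f and 159 were lower, where counting error alone gave 2 and 1.2. Chromosome 4 held 37 of the lower windows out of 124 tested, 3L held 42, 2R 29, X 24 and 2L 22, while 3R, the arm with the most windows, held 5. Within 1.5 Mb of the centromere-side end of the large arms lay 74 of the 159 lower windows and 12 of the 35 higher ones. The preimmune libraries, which are separate libraries from the same genotypes, called 29 of the 35 higher and 105 of the 159 lower windows the same way, and 1 window the other way.

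The called windows formed 137 regions, of which 112 were single windows. The longest was X 2690001 to 2820000, where su(Hw)f input held 259 reads and wild-type input 11597. The ratio was 0.0151 in input (0.0133 to 0.0171) and 0.0321 in preimmune (0.0295 to 0.0348), against 1.06 in the flanking 100 kb on each side in input. The single window X 2690001 to 2691000 held 377 of the 609 su(Hw)f preimmune reads in the region. Without it, an alternative chosen after seeing the data, the ratios were 0.0152 in input (0.0134 to 0.0172) and 0.0127 in preimmune (0.0111 to 0.0145). Most su(Hw)f reads that were left lay at the end of the region, so these ratios are not an even residue. X 2818001 to 2820000 held 217 reads in su(Hw)f input and 204 in su(Hw)f preimmune. Wild type held 220 in input and 174 in preimmune there. The next longest region was 2L 12870001 to 12940000, which was 1.76-fold higher in su(Hw)f in input (1.71 to 1.81) and 1.75-fold in preimmune (1.70 to 1.80). There su(Hw)f input stood at 1.92 times the library median and wild-type input at 0.938 times. These multiples rest on the median window and not on the arm totals, so they do not give the ratio of 1.76. At the tip of 3L, 20001 to 70000 was 3.70-fold higher in su(Hw)f in input (3.43 to 4.0) and 5.51-fold in preimmune (5.06 to 6.01).

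X 21600001 to 21640000 was 5.37-fold higher in su(Hw)f input (4.52 to 6.44) and 3.70-fold in preimmune. It lies near the centromere-side end of X, at 0.0327 times the median in wild-type input and 0.204 times in su(Hw)f input. On chromosome 4, 250001 to 290000, 80001 to 120000, 300001 to 340000 and 350001 to 380000 had input ratios of 0.583, 0.624, 0.630 and 0.629, and preimmune ratios of 0.670, 0.603, 0.682 and 0.585. In preimmune, 250001 to 290000 and 300001 to 340000 were short of a 1.5-fold difference. The 100 kb flanks of 250001 to 290000 were at 0.687 in input, but they include 300001 to 340000 and 350001 to 380000. Over all 124 windows of 10 kb tested on chromosome 4, the median log2 ratio in input was -0.453, with 37 called lower. The shift was therefore not confined to the called windows. On 2R, 1150001 to 1180000 was at 0.0817 in input (0.0701 to 0.0948) and 0.0881 in preimmune (0.0767 to 0.101). 2R 770001 to 810000 was at 0.628 in input (0.589 to 0.670) and 0.731 in preimmune (0.691 to 0.773), short of a 1.5-fold difference. A region tied in length with the last of the 10, 4 1130001 to 1160000, was at 0.634 in input and 0.737 in preimmune, also short of 1.5-fold in preimmune.

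**Figure D2:**
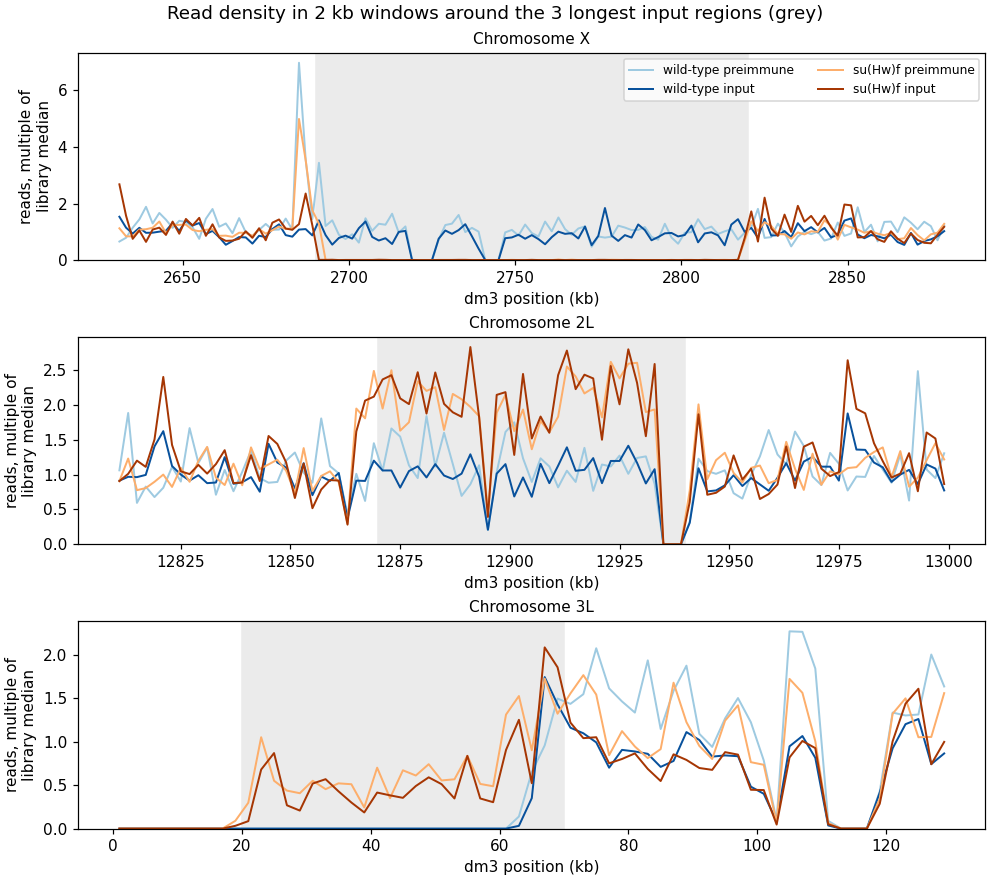
Reads per 2 kb window as multiples of each library's median, against dm3 position in kb, for the 4 libraries around the 3 longest regions (grey). Both su(Hw)f libraries fall to near 0 on X, both rise on 2L to 1.92 times the median in input, and both wild-type libraries hold no reads on 3L up to position 62000.

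At 1 kb, 157 of 113318 windows were absent in su(Hw)f and 90 of 113387 were absent in wild type, in 21 and 29 stretches. These stretches were defined after the data were seen. The longest absent in su(Hw)f was X 2691001 to 2818000, with 28 preimmune and 41 input reads against 10770 and 11266 in wild type. That is 0.156% (0.104% to 0.226%) and 0.246% (0.176% to 0.334%) of the scaled wild-type reads. The window before this stretch, X 2690001 to 2691000, held 1 su(Hw)f input read against 111 in wild-type input. Its 377 su(Hw)f preimmune reads kept it out of the stretch. Neither su(Hw)f library held reads at X 2689601 to 2690000, so the loss in input began before 2691001. On 2R, 1152001 to 1171000 kept 3 preimmune and 7 input reads in su(Hw)f, against 1372 and 1430 in wild type.

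The longest stretch absent in wild type was 3L 20001 to 62000. Wild type had 0 reads there in both libraries, and su(Hw)f had 3706 in preimmune and 2683 in input. The exact interval for wild-type input reached 0.204% of the scaled su(Hw)f reads, and a floor of 3 counts came to 0.165%. Its own level was 0.456 times the library median in input and 0.588 times in preimmune. X 21620001 to 21639000 held 4 preimmune and 2 input reads in wild type against 911 and 805 in su(Hw)f. 3L 23102001 to 23112000 held 0 and 1 against 418 and 435.

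Preimmune over input asked what the control serum recovers in the absence of the antibody. In wild type, 11102 of 113907 windows of 1 kb were higher in preimmune and 11403 were lower, where counting error alone gave 29.4 and 36.4. In su(Hw)f, 7772 of 113923 were higher and 3819 were lower, against 29.25 and 27.55. On chromosome 4, 433 of 1169 windows were higher and 11 lower in wild type, and 424 of 1160 were higher and 4 lower in su(Hw)f. The median log2 ratio over all windows in su(Hw)f was 0.14. Scaling by that median turned the su(Hw)f split from 67.1% higher to 43.6% higher (4801 higher and 6217 lower), so the balance of directions rests on the scaling.

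The profiles of the genotypes were correlated. The log2 ratios correlated at r = 0.698 (Spearman rho = 0.690) over 113592 windows, which are not independent replicates. The ratios of the genotypes share no library. To remove the trend with the input of the other genotype, counts were thinned so that this step shared no input reads. In the thinned counts r was 0.676, and it fell to 0.201 once the trend was removed. Input is the denominator of the ratio, so this drop does not separate a library trend from preimmune enrichment that follows input. Of the windows tested in both, 3721 were higher in both genotypes where independent lists would share 744, and 2554 were lower in both where independent lists would share 380. In 5 windows preimmune was higher in wild type and lower in su(Hw)f, and in 14 the reverse.

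**Figure D3:**
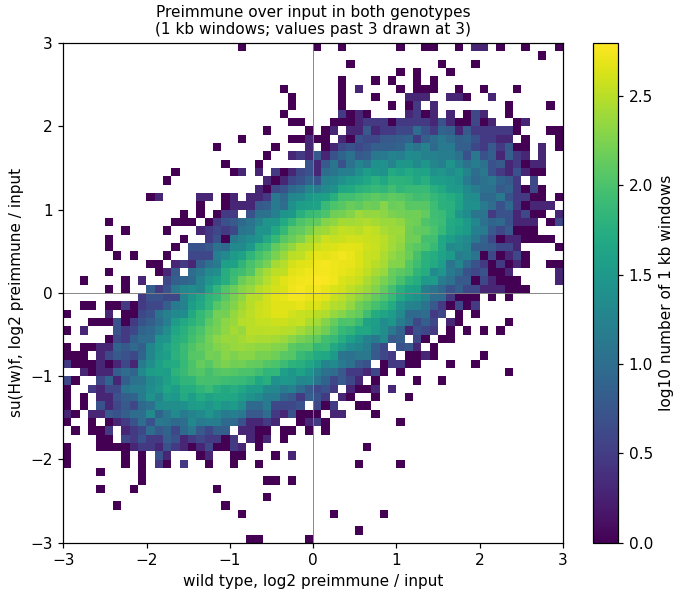
Number of 1 kb windows (colour, log10) by log2 preimmune over input in wild type (x axis) and in su(Hw)f (y axis), 1 library per group. The cloud rises along the diagonal, with r = 0.698 over 113592 windows before any trend with input is removed.

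Among the 10 windows with the highest mean log2 ratio over the genotypes, 2 lay within 10 kb of each other on X. X 2690001 to 2691000 ranked first, at 4.80-fold in wild type (3.89 to 5.96) and 387-fold in su(Hw)f (69.1 to 15343), with 377 preimmune reads against 1 input read in su(Hw)f. X 2684001 to 2685000 was 7.39-fold higher in preimmune in wild type (6.02 to 9.16) and 4.85-fold in su(Hw)f (4.07 to 5.81). X 11943001 to 11944000 was 11.5-fold higher in wild type (7.41 to 18.7) and 3.88-fold in su(Hw)f (2.28 to 6.94), and 3L 5043001 to 5044000 10.2-fold and 3.36-fold. 3L 6706001 to 6707000 was 6.51-fold higher in wild type (4.59 to 9.45) and 7.08-fold in su(Hw)f (3.50 to 16.2).

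The other 5 rested on few input reads, from 1 to 4 in su(Hw)f and from 2 to 23 in wild type. They were 3L 24080001 to 24081000, X 22022001 to 22023000, 3L 17510001 to 17511000, 2L 13599001 to 13600000 and 3L 21613001 to 21614000. In wild type their ratios were 17.9 (4.56 to 154.5), 6.01 (2.27 to 20.05), 4.05 (1.58 to 12.3), 3.82 (1.84 to 8.68) and 3.92 (2.44 to 6.54). In su(Hw)f they were 10.6 (3.31 to 54.3), 25.7 (4.21 to 1055), 13.4 (3.34 to 116), 10.8 (2.64 to 94.9) and 9.25 (3.32 to 35.8). The 5 lowest were 2R 2174001 to 2175000 (ratios 0.0963 in wild type and 0.234 in su(Hw)f), 3R 2244001 to 2245000 (0.105 and 0.286), 3L 13423001 to 13424000 (0.191 and 0.170), X 5732001 to 5733000 (0.174 and 0.195) and X 1893001 to 1894000 (0.134 and 0.256). The first 2 of these rested on 2 and 5 wild-type preimmune reads, with wild-type intervals of 0.0110 to 0.388 and 0.0328 to 0.260.

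**Figure D4:**
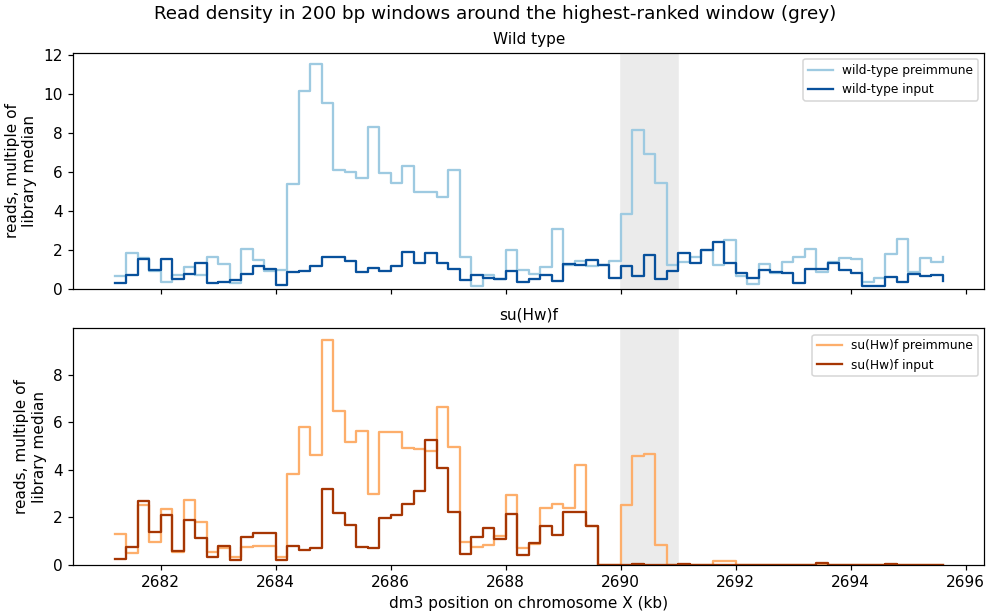
Reads per 200 bp window as multiples of each library's median, against dm3 position on X in kb, with wild type above and su(Hw)f below; grey marks X 2690001 to 2691000. In su(Hw)f the window holds 377 preimmune reads and 1 input read.

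Preimmune also differed between genotypes. Of 114099 windows of 1 kb, 6798 were higher in su(Hw)f preimmune and 7611 were lower, against 39.55 and 20.45 from counting error. Chromosome 4 held 272 lower windows and 18 higher ones among 1173. In the windows that were lower in preimmune, the median log2 ratio of su(Hw)f over wild type was -1.27 in preimmune and -0.57 in input, and input called 1424 of the 7611 lower as well. In the windows that were higher, the medians were 1.20 and 0.23, and input called 196 of 6798 the same way and 13 the opposite way. These windows were chosen by their preimmune ratio, so the preimmune medians lie past 1 in size by that choice. They cannot be set against the input medians as a larger difference. The share of all 1 kb windows that input called is not given here, so the overlaps have no base rate.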

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

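The tests of counting error, of the library-wide trend in preimmune over input and of the window on X were chosen after the results they bear on had been seen, and the matching test for chromosome 4 was written before its result was seen. Reads on the Y scaffold YHet, which no comparison used, were above the 3 counts that a count of 0 allows. They numbered 26 in wild-type preimmune, 27 in wild-type input, 31 in su(Hw)f preimmune and 33 in su(Hw)f input, in libraries made from females. The fullest 100 bp window held 17, 8, 14 and 17 of these reads in that order. Between 99.5% and 99.8% of YHet windows were empty, so the reads were not spread along the scaffold.

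Many 1 kb windows differed at least 2-fold between preimmune and input. Counting error alone falls far short, since draws at the pooled rate gave 65.8 windows in wild type where 22505 were called. A trend shared by the input libraries stays open. In counts thinned so that no reads were shared, wild-type preimmune over input correlated at r = -0.72 with the input of su(Hw)f. For su(Hw)f preimmune over input and the input of wild type, r was -0.59. Removing that trend left 27.4% of the windows past 2-fold in wild type and 34.0% in su(Hw)f, and the correlation between genotypes fell from 0.676 to 0.201. Base composition, PCR or shearing may produce such a trend, as may chromatin state, and without a dm3 sequence these were not separated. Input is the denominator of the ratio, so structure that the inputs share gives a negative r whatever its cause. Removing the trend also removes any preimmune enrichment that follows input. The drop was therefore likely in advance and does not decide between these causes.

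In su(Hw)f, the preimmune library held 377 reads at X 2690001 to 2691000 where the input held 1, inside DNA the mutant input lacks. Against wild-type chromatin mixed into the library, su(Hw)f preimmune came to 0.159% (0.105% to 0.230%) of wild-type preimmune over 109 other windows of the region that the inputs alone called absent, and to 49.1% in this window. Against a copy elsewhere in the mutant genome, none of 74739 other windows with at least 100 reads in wild-type input and in su(Hw)f preimmune had fewer than 41 reads in su(Hw)f input. DNA from outside the flies that entered at the preimmune step stays open as a hypothesis. The preimmune excess here relative to 2 nearby windows, X 2684001 to 2685000 and X 2685001 to 2686000, was 0.347 in wild type and 0.327 in su(Hw)f, a ratio of 0.941 (0.780 to 1.13), as 1 common source could give.

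Chromosome 4 was lower in su(Hw)f input, with a median log2 ratio of -0.51 over 1130 windows of 1 kb against -0.05 on the other arms outside their last 1.5 Mb. Windows of other arms matched on wild-type preimmune over input left a difference of -0.24 (-0.28 to -0.21), and those matched on su(Hw)f preimmune over input left -0.19 (-0.23 to -0.16). The library trend and a difference in chromosome 4 DNA between the genotypes cannot be told apart, because the matchings fall on either side of the bound set beforehand and matching on noisy ratios removes a trend only in part. Each matching ratio also contains 1 of the inputs being compared, which may move the matched difference, and this effect was not separated. The genotype itself, together with its strain background, stays among the untested explanations.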

How the results depend on the processing

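No paired analysis was possible because the labels give 1 sample per group and no replicate numbers. With windows 5 times larger, fewer windows are tested, but every count fell by more than 5 times, so the share of windows called fell too. The counts became 4 higher and 10 lower for input, and 489 and 530 for wild-type preimmune over input. They became 201 and 79 for su(Hw)f preimmune over input, and 116 and 233 for preimmune between genotypes. The split of the last moved from 47.2% to 33.2% higher. Scaling by the median ratio gave 4801 higher and 6217 lower for su(Hw)f preimmune over input, since the median lies at 0.14 in log2. Calling lower input windows in preimmune too, an alternative added after seeing the data, left 105. Agreement between genotypes was 0.798 in 5 kb windows. For chromosome 4, scaling by the median ratio over 1 kb windows gave preimmune over input of 1.60 in wild type and 1.43 in su(Hw)f, and su(Hw)f over wild type of 0.787 in input and 0.708 in preimmune. For 2RHet it gave 1.28, 1.21, 0.693 and 0.662 in that order, and for X 0.956, 0.854, 1.08 and 0.967. Scaling to all reads gave X ratios of 0.963 and 0.937 for preimmune over input in wild type and su(Hw)f, and 1.034 for su(Hw)f over wild type in input. The su(Hw)f over wild-type ratio on X in preimmune, next to 1 in the main scaling, changed side to 1.006. Without the highest 0.1% of windows the share of reads on X was 17.37% in wild-type preimmune, 18.04% in wild-type input, 17.47% in su(Hw)f preimmune and 18.60% in su(Hw)f input, and chromosome 4 took 0.488% in su(Hw)f input. The cause of these shifts in shares was not tested. The other 66 values for the main comparisons stayed within 1.5 times, or within their counting interval or 2 decimals where they are not counts. Of 92 values for named regions under another setting, 84 stayed within their counting interval, 8 left it and none changed side. Most of these settings only changed the scaling, which moves a ratio little next to its interval. Preimmune in place of input left the interval in most of the 10 longest regions. It stayed within for 2L 12870001 to 12940000, 4 80001 to 120000 and 2R 1150001 to 1180000. The X region without its highest-ranked window also left the interval in preimmune. The alternatives for the su(Hw) locus, gene lists, annotation classes and Su(Hw) motif sites were not run, since no dm3 sequence or annotation was used here. Depth limits 1 kb windows with few reads, and the scatter between libraries made in the same way is unknown.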

Other observations

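The focal windows, defined after the data were seen, marked short segments that stood far above the rest of the genome. X 8188501 to 8190000 was high in all 4 libraries, at 23.5 and 18.5 times the median in wild-type and su(Hw)f preimmune and at 9.30 and 9.04 times in their inputs. 2R 995501 to 997500 was high in wild type alone, at 9.51 times the median in preimmune and 9.72 times in input, against 1.41 and 1.11 in su(Hw)f. Other segments were high in su(Hw)f alone. 2R 10736501 to 10738000 stood at 7.48 times in preimmune and 9.56 times in input, 3L 20816001 to 20816500 at 12.1 and 7.64 times, and 3R 24310501 to 24311500 at 6.09 and 6.5 times. Wild type had 1.04 and 1.42, 1.38 and 0.691, and 0.856 and 1.11 times at the same 3 segments.

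X 19569001 to 19573000 was 2.80-fold higher in su(Hw)f in input (2.60 to 3.02) and 2.85-fold in preimmune (2.54 to 3.21). Of 55 focal windows of 500 bp, 24 reached 6 times the median in su(Hw)f input alone, with medians over these windows of 6.66 in su(Hw)f input, 2.96 in wild-type input, 2.69 in su(Hw)f preimmune and 1.01 in wild-type preimmune. In another 16, wild-type preimmune alone reached 6 times its median, with medians over these windows of 6.26 in wild-type preimmune, 1.04 in wild-type input, 1.72 in su(Hw)f preimmune and 0.593 in su(Hw)f input. An example is 2L 18330501 to 18331000, with 358 reads in wild-type preimmune and 29 in wild-type input. The bar was not equal across libraries, because the median lay furthest below the mean in su(Hw)f input. The median 100 bp window held 14 reads against a mean of 16.9 there, and 11 against 11.4 in wild-type input. It held 9 against 9.85 in wild-type preimmune and 15 against 16.4 in su(Hw)f preimmune. This lower bar may raise the count for su(Hw)f input.

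In 50 kb windows, 3L 13850001 to 13900000 was lower in su(Hw)f, with ratios of 0.649 in input (0.629 to 0.670) and 0.586 in preimmune. Wild type stood at 1.47 times its median there in input, and su(Hw)f at 1.11 times. These multiples rest on the median window and not on the arm totals, so they do not give the ratio of 0.649. Density fell toward the centromere-side end of most arms. In the last 1 Mb it was 0.316 of the arm median on 3L in wild-type input and 0.280 in su(Hw)f input, and on 3R it was 0.937 and 0.951.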
